A study of Homo sapiens with 15 samples.

How the data were processed

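RNA was measured in MM.1S cells, a human multiple myeloma line, after 6 h with DMSO, A-485, GNE-781, A-485 and GNE-781 together, or dCBP-1, each compound at 100 nM. There were 3 libraries in each of the 5 groups, 15 in all. Per the labels, cells were lysed in Trizol with ERCC spike-in controls, RNA was purified on RNeasy columns, and libraries were made with the Lexogen QuantSeq kit for the 3′ ends of mRNA, a method in which reads per gene do not scale with transcript length. The labels give the hg19 build. They give no aligner, counting tool, annotation release or normalization tool, and the strandedness of counting is not stated in the sources used here, so reads from the opposite strand of a gene cannot be ruled out in its value. Samples were grouped by their titles, and replicates were not pooled. The treatment field of 2 combination libraries names GNE-782 and GNE-783 where titles and the treatment protocol name GNE-781, and the molecule field of all libraries says genomic DNA. Both were taken as label errors, which was not tested.

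The deposited values are a gene-level signal per library, which the authors call normalized read counts. Tested on the values, every entry of a library was a whole multiple of 1 step (100% of values within a tolerance of 0.01 of a whole read), and the step differed between libraries. The values are therefore read counts divided by 1 factor per library, and the reads were recovered by multiplying back. How those factors were obtained is not stated. Relative to them, median-ratio factors ran from 0.874 to 1.09. The table used here holds 47459 gene rows with values and 1 last row with an identifier and no value, so genes with later identifiers were not analysed here. No ERCC rows were in it, so the spike-in share and scaling to the spike-ins, both planned, were not run, and no value here is a measure of RNA per cell. Symbols were available for 45779 of the identifiers (96.5%). Genome positions are not given, because the values refer to hg19 and the annotation used here for symbols and transcript ends does not.

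Values were taken as log2(value + 1). Genes with a value of 5 or more in at least 3 of the 15 libraries were tested, 16104 in all. The test was limma-trend (limma 3.58.1 in R 4.3.3) in 1 model of the 5 group means over the 15 libraries, two-sided, with Benjamini-Hochberg adjustment over the genes tested in each comparison and a call at an adjusted p below 0.05. Genes called with a positive or negative log2 fold change are said to have risen or fallen. Errors of group means are SD and errors of log2 fold changes are SE. The comparisons were each treatment with DMSO, dCBP-1 with each of the inhibitor treatments, the inhibitor treatments with each other, and non-additivity, which is the combination minus A-485 minus GNE-781 plus DMSO on the log2 scale. Nothing in the labels says that replicates were separate cultures, so the p-values measure only the spread between these libraries.

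Between recovered reads of replicates the chi-square per degree of freedom ran from 5.30 to 42.2, so replicates differed by more than counting error. Library depth was 13.10 to 18.29 M reads. A count of 3 reads is the upper limit that 0 reads allows in a library, and it covers counting error only. The replicate number was not used as a pairing.

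Gene lists, 25 in number, were tested in 5 comparisons with camera (limma, preset correlation between genes of 0.01), which ranks a list against the other genes tested, with adjustment over the 125 tests. A correlation estimated from the data was used beside it. For each list, members called over all genes tested are counted, and members called when p-values were adjusted over the list alone. Correlations of fold changes between comparisons that share the DMSO libraries were set beside 100 simulated pairs of unchanged groups compared with the same DMSO libraries.

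The rule for named genes, the lists, the tests and most alternatives were fixed before the data were examined. Named are, in each comparison with DMSO, the 10 called genes with the largest rise and the 10 with the largest fall among genes whose treated libraries all lay on 1 side of all DMSO libraries and whose mean lay at or above the median of genes tested; in the other comparisons 5 and 5; of each list described, up to 4 members with the smallest p; and CREBBP, EP300, MYC and IRF4 throughout. Unnamed transcripts, clone names and antisense genes were skipped. The text gives a part of these genes and summarises the rest.

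Alternatives were TMM, median-ratio and quantile scaling, pseudocounts of 0.25 and 5, no filter, a filter at 20, only the groups compared, a replicate block, a robust variance prior, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and each library left out in turn. Added after seeing the data were removal of the trend with the GC content of the last 500 bases of transcripts, a fit without DMSO replicates 1 and 2 together, edgeR and DESeq2 for comparisons between treatments, and median-ratio scaling for the correlations. Where leaving out libraries left a group with 1, limma pooled the spread, and the lone library was assumed to vary like the other groups.

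The pipeline was tested on simulated data with known changes of 1.5, 2 and 4 fold in 200 genes. For A-485 against DMSO it recovered 46.3%, 61.2% and 84.8% of them, for dCBP-1 against DMSO 43.3%, 61.2% and 68.2%, for dCBP-1 against the combination 29.9%, 52.2% and 81.8%, and for non-additivity 11.9%, 44.8% and 62.1%. Of the simulated calls, 9.2%, 4.2%, 5.2% and 3.7% were false in these 4 comparisons, each simulated once with genes that varied independently of each other. Among changed genes at or above the median level, 4-fold changes were recovered in 100% in each comparison. There 2-fold changes were recovered in 94.4%, 100%, 96.7% and 77.8%, in the same order. The real dCBP-1 comparison with DMSO called 6092 genes, so recovery with 200 changed genes need not hold for it. Shifts that many genes of a library share were not part of this test. In the 100 simulations of unchanged groups, which keep such shifts, A-485 against DMSO had 2.56 calls on average and 204 at most. The highest counts against DMSO were 217 for GNE-781, 249 for the combination and 375 for dCBP-1. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.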

Results

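Transcripts were measured by 3′ end RNA sequencing in MM.1S cells, a multiple myeloma line in which MAF is translocated to the immunoglobulin heavy chain locus. Cells were treated for 6 h with DMSO, A-485, GNE-781, A-485 and GNE-781 together (the combination), or dCBP-1. A-485 inhibits the acetyltransferase activity of the paralogous coactivators CBP and p300, and GNE-781 their bromodomains. dCBP-1 is a degrader of both proteins that joins a bromodomain ligand of the GNE-781 type to a cereblon ligand. Each of the 5 groups had 3 libraries. Depth ran from 14.99 to 17.31 M reads for DMSO, 16.37 to 17.58 for A-485, 13.16 to 17.21 for GNE-781, 14.66 to 18.29 for the combination and 13.10 to 18.08 for dCBP-1. Levels are normalized read counts.

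DMSO replicates 1 and 2 stood apart from the other 13 libraries in quality measures. Mitochondrially encoded genes took 23.1% and 19.7% of their reads, against 16.4% in DMSO replicate 3 and 14.3% to 17.0% in the treated libraries. At an equal depth of 13.1 M reads, 16287 and 17386 genes had a read in DMSO replicates 1 and 2, against 19676 in DMSO replicate 3 and 18727 to 20578 in the treated libraries. Principal components were taken over the tested genes at or above the median level. The first held 59.7% of their variance and placed dCBP-1 at 1 end and DMSO at the other, and the second held 11.9%.

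**Figure D1:**
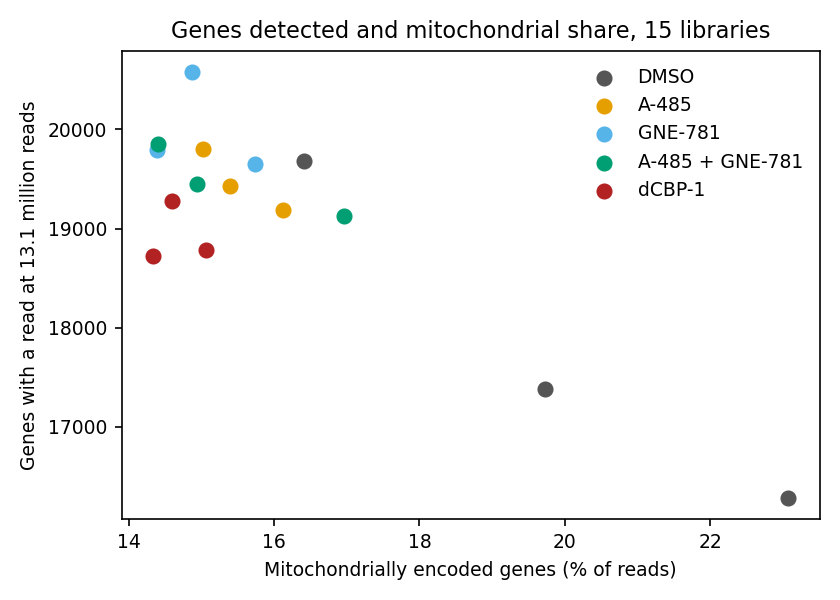
Genes with at least 1 read at 13.1 M reads (y axis) against the percent of reads from mitochondrially encoded genes (x axis) for the 15 libraries, coloured by group. DMSO replicates 1 and 2 lie at 23.1% and 19.7% with fewer genes than any other library.

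A-485 alone addressed the effect of blocking the acetyltransferase activity. NFKB2 (ENSG00000077150), which encodes a precursor subunit of NF-kB, fell from 1998 ± 364 to 782 ± 143 normalized read counts (mean ± SD, n = 3), a log2 fold change of −1.35 ± 0.15 (SE; limma adjusted p = 7.9e-06). PCDH1, a protocadherin, fell by 1.25 on the log2 scale (limma adjusted p = 0.00018). In all, 345 of 16104 genes were called, 56 higher and 289 lower, and 37 and 49 of these differed at least 2 fold. MYC had a log2 fold change of −0.83, with a 95% interval of −1.51 to −0.15 (limma adjusted p = 0.21). IRF4, a transcription factor on which myeloma cells depend, had −0.33, with an interval of −0.72 to 0.07.

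Several lists lay lower than other genes with A-485, although few of their members were called. Of 11 MAF targets, 0 rose and 4 fell (4 adjusted over the list alone). The median was −0.41 (camera adjusted p = 0.00027, adjusted p = 0.28 with an estimated correlation). Of 28 plasma cell surface and secretory markers, 3 fell (7 adjusted over the list alone). The median was −0.27 (camera adjusted p = 1.8e-05, adjusted p = 0.39 with an estimated correlation). Of 56 MYC targets, 4 fell, the same number adjusted over the list alone. Among them was PPAN, a ribosome biogenesis factor whose exons also belong to a readthrough transcript (−0.91 ± 0.17, and −0.73 without DMSO replicates 1 and 2 together, adjusted p = 0.24). The call of this list (camera adjusted p = 0.0077, adjusted p = 0.80 with an estimated correlation) ended without DMSO replicate 3 (adjusted p = 0.086) or A-485 replicate 3 (adjusted p = 0.078). Mitochondrially encoded genes took a larger share of reads in DMSO replicates 1 and 2. Against all DMSO libraries 1 of these 15 genes fell with A-485, and 7 adjusted over the list alone, with a median of −0.48 (camera adjusted p = 7.4e-05, adjusted p = 0.33 with an estimated correlation). The 10 largest named rises, TPM1 first (1.10 ± 0.23, adjusted p = 0.0081), each lost their call with 1 library or another left out. TPM1 had 0.90 without DMSO replicate 1 (adjusted p = 0.053), 0.92 without DMSO replicate 2 (adjusted p = 0.090) and 0.99 without A-485 replicate 2 (adjusted p = 0.061). It had 0.35 without DMSO replicates 1 and 2 together (adjusted p = 0.59), and its call also ended with only the groups compared (adjusted p = 0.11).

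The count for A-485 was 218, 69 and 1138 without DMSO replicates 1, 2 and 3, the last with 683 higher and 455 lower, and 212, 132 and 184 without A-485 replicates 1, 2 and 3. Without DMSO replicates 1 and 2 together it was 12, and NFKB2 and PCDH1 alone among the 10 largest named falls stayed called. It was also 178 with no filter, 78 with only the groups compared and 852 with DESeq2, and the split of 56 higher and 289 lower became 164 and 193 under TMM, 137 and 245 under median-ratio scaling and 145 and 185 under quantile normalization.

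GNE-781 alone addressed the effect of blocking the bromodomains. IRF4 (ENSG00000137265) fell from 2335 ± 133 to 866 ± 153 normalized read counts (log2 fold change −1.44 ± 0.19, limma adjusted p = 6.7e-06) and MYC (ENSG00000136997) fell from 1448 ± 246 to 434 ± 99.6 (−1.75 ± 0.33, adjusted p = 0.00053). TNFRSF17, the B cell maturation antigen of plasma cells, fell by 1.93 ± 0.15 (adjusted p = 5.8e-10). CXCR3, a chemokine receptor, fell (−1.83 ± 0.21), as did PTK2B, a focal adhesion kinase family member (−1.69 ± 0.13). EGR1 (ENSG00000120738), an immediate early transcription factor, rose from 42.8 ± 16.6 to 233 ± 58.3 (2.44 ± 0.24, adjusted p = 1.2e-07). LIMA1, an actin-binding protein, rose by 1.34 ± 0.17, and TPM1, a tropomyosin, by 1.60 ± 0.23.

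Of 30 transcription factors of myeloma and plasma cells, 16 fell and 0 rose with GNE-781 (19 lower adjusted over the list alone). The median was −0.59 (camera adjusted p = 1.0e-13, adjusted p = 0.31 with an estimated correlation). PRDM1, which drives plasma cell differentiation (−1.31 ± 0.13), MAF (−1.26 ± 0.14) and the coactivator POU2AF1 (−1.28 ± 0.15) were among the 16. Of 28 plasma cell surface and secretory markers, 10 fell (12 adjusted over the list alone). The syndecan SDC1 (−1.10 ± 0.12) and the chemokine receptor CCR1 (−1.38 ± 0.13) were among these (list camera adjusted p = 4.4e-11, adjusted p = 0.18 with an estimated correlation). Of 56 MYC targets, 16 fell and 1 rose (22 and 1 adjusted over the list alone). The median was −0.23 (camera adjusted p = 1.4e-05, adjusted p = 0.55 with an estimated correlation). Of 16 BCL2 family genes, 7 fell and 1 rose, as many adjusted over the list alone. The antiapoptotic BCL2L1 (−1.39 ± 0.17) and BCL2 (−0.85 ± 0.15) and the proapoptotic BMF (−0.98 ± 0.17) fell (list camera adjusted p = 0.00018, adjusted p = 0.33 with an estimated correlation). Of the 15 mitochondrially encoded genes, with their larger share in DMSO replicates 1 and 2, 4 fell (7 lower and 1 higher adjusted over the list alone). The median was −0.49 (camera adjusted p = 0.0014, adjusted p = 0.45 with an estimated correlation).

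With GNE-781, 2679 genes were called, 1260 higher and 1419 lower, 380 and 342 of them at least 2 fold. The balance turned to 2375 higher and 1314 lower without DMSO replicate 3, 1866 and 1744 under TMM and 1905 and 1639 under quantile normalization. The count was 1607 without DMSO replicate 2, 1467 and 1649 without GNE-781 replicates 1 and 2, and 883 (159 higher, 724 lower) without DMSO replicates 1 and 2 together. CREBBP, the gene of CBP, rose by 0.55 ± 0.15 (adjusted p = 0.0094), a call that ended without DMSO replicate 2 (0.44, adjusted p = 0.081) or GNE-781 replicate 1 (0.49, adjusted p = 0.062) and without DMSO replicates 1 and 2 together (0.40, adjusted p = 0.27).

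The combination addressed the effect of blocking both domains. MYC fell to 268 ± 129 normalized read counts (−2.53 ± 0.33, limma adjusted p = 4.2e-06), IRF4 to 688 ± 211 (−1.81 ± 0.19, adjusted p = 1.4e-07) and TNFRSF17 to 1275 ± 80.3 (−2.23 ± 0.15, adjusted p = 3.5e-11). EGR1 rose to 340 ± 69.4 (3.0 ± 0.24, adjusted p = 1.4e-09), TPM1 by 1.79 ± 0.23, and PLIN3, a lipid droplet protein, by 1.45 ± 0.16. HDAC9, a class IIa deacetylase (−1.95 ± 0.19), IGFBP3, which binds insulin-like growth factors (−2.06 ± 0.22), and RARA, a retinoic acid receptor (−2.21 ± 0.23), fell. CREBBP rose by 0.58 ± 0.15 (adjusted p = 0.0046), but had 0.43 without DMSO replicates 1 and 2 together (adjusted p = 0.21).

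Of the 30 transcription factors, 18 fell and 0 rose with the combination (19 lower adjusted over the list alone). The median was −0.59 (camera adjusted p = 5.5e-14, adjusted p = 0.31 with an estimated correlation). Of 11 MAF targets, 6 fell (7 adjusted over the list alone), including DEPTOR, an inhibitor of mTOR (−1.05 ± 0.17), and the kinase NUAK1 (−1.17 ± 0.16). The median was −1.05 (camera adjusted p = 1.9e-07, adjusted p = 0.10 with an estimated correlation). Of 56 MYC targets, 25 fell and 2 rose, with the same counts adjusted over the list alone. RRP9, a ribosomal RNA processing factor, fell (−1.14 ± 0.14), and the list's median was −0.28 (camera adjusted p = 3.4e-08, adjusted p = 0.39 with an estimated correlation). Of 36 genes of G2/M and mitosis, 15 rose and 1 fell (16 and 1 adjusted over the list alone). The kinetochore gene NDC80 (1.0 ± 0.17) and AURKA, a mitotic kinase (0.85 ± 0.16), rose, but without DMSO replicates 1 and 2 together they had 0.71 (adjusted p = 0.069) and 0.38 (adjusted p = 0.23). The median was 0.32 (camera adjusted p = 0.00033, adjusted p = 0.76 with an estimated correlation). In all, 3383 genes were called, 1837 higher and 1546 lower, 560 and 436 at least 2 fold. The split was 2850 higher and 1427 lower without DMSO replicate 3 and 1832 and 1087 without combination replicate 1, and it turned to 1173 and 1422 without DMSO replicate 1, 1314 and 1574 without combination replicate 3 and 2057 and 2126 under median-ratio scaling. The count was 2215 (1088 higher, 1127 lower) without DMSO replicate 2, 2050 (885 and 1165) without combination replicate 2, 2163 (968 and 1195) with only the groups compared, and 1064 (284 higher, 780 lower) without DMSO replicates 1 and 2 together.

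**Figure D2:**
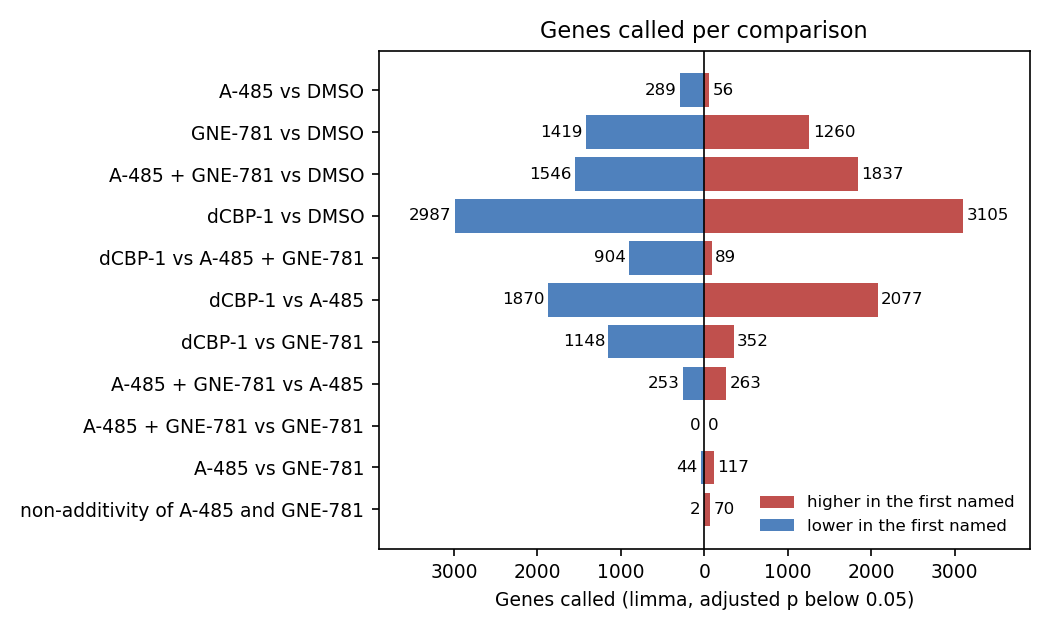
Genes called (limma adjusted p below 0.05) as higher (red, right) or lower (blue, left) in the first named group, for each comparison; non-additivity is the combination against the sum of both inhibitors. dCBP-1 against DMSO has 3105 higher and 2987 lower, and the combination against GNE-781 has 0.

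dCBP-1 addressed the effect of a compound made to remove the CBP and p300 proteins. These libraries do not measure the proteins. No group had a cereblon ligand alone, so effects of that part of dCBP-1 cannot be told apart. MYC fell from 1448 ± 246 to 4.76 ± 3.23 normalized read counts, a log2 fold change of −8.17 ± 0.33 (limma adjusted p = 4.2e-18). It had 8, 7 and 1 reads in the 3 dCBP-1 libraries, and the size of its change followed the pseudocount, from −8.48 with 0.25 to −7.26 with 5. MAF fell from 16390 ± 1437 to 649 ± 131 (−4.67 ± 0.14, adjusted p = 2.7e-20), PRDM1 from 9190 ± 649 to 492 ± 77.8 (−4.23 ± 0.13, adjusted p = 2.7e-20) and IRF4 from 2335 ± 133 to 232 ± 58.0 (−3.35 ± 0.19, adjusted p = 1.5e-14). TRIB1, a pseudokinase, fell from 616 ± 62.3 to 13.4 ± 2.28 (−5.43 ± 0.18). CYP26A1, which clears retinoic acid (−5.19 ± 0.29), and DUSP5, a phosphatase of ERK (−4.63 ± 0.17), also fell. EGR1 rose from 42.8 ± 16.6 to 2691 ± 98.6 (6.00 ± 0.24, adjusted p = 4.1e-18), and ETV5, an ETS transcription factor, rose by 2.39 ± 0.16 (adjusted p = 2.7e-13). CREBBP rose by 0.85 ± 0.15 (adjusted p = 2.9e-05). EP300, the gene of p300, rose from 1193 ± 106 to 1607 ± 395, by 0.41 ± 0.16 (adjusted p = 0.049).

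**Figure D3:**
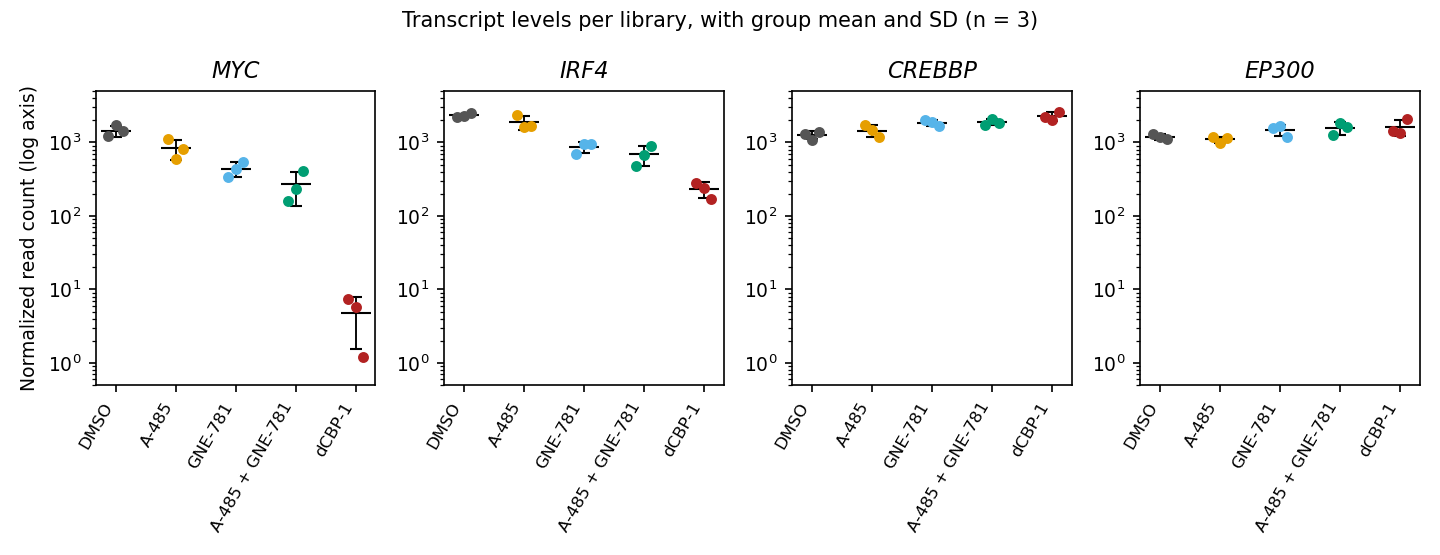
Normalized read counts on a log axis of MYC, IRF4, CREBBP and EP300 in each library (points), with the group mean (long bar) and SD (short bars, n = 3). MYC means run from 1448 with DMSO to 4.76 with dCBP-1, and CREBBP means from 1264 to 2274.

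Of the 30 transcription factors of myeloma and plasma cells, 26 fell and 0 rose with dCBP-1 (26 lower adjusted over the list alone), including KLF13 (−3.87 ± 0.15). The median was −1.93 (camera adjusted p = 5.8e-29, adjusted p = 0.10 with an estimated correlation). Of 11 MAF targets, 10 fell, the same number adjusted over the list alone, with DEPTOR at −4.05 ± 0.17 and CCR1 at −3.96 ± 0.13. Their median was −2.62, and the call held with an estimated correlation (camera adjusted p = 1.3e-12, adjusted p = 0.038 with an estimated correlation). Of 28 plasma cell surface and secretory markers, 21 fell and 0 rose (22 lower adjusted over the list alone), with TNFRSF17 at −4.01 ± 0.15, TNFRSF13B, a related receptor, at −3.44 ± 0.13 and the costimulatory receptor CD28 at −3.05 ± 0.15. The median was −0.98 (camera adjusted p = 3.7e-15, adjusted p = 0.10 with an estimated correlation). Of 56 MYC targets, 37 fell and 2 rose (40 and 2 adjusted over the list alone), with PPAN at −2.75 ± 0.17 and WDR43, a nucleolar protein, at −1.73 ± 0.13. The median was −0.67 (camera adjusted p = 1.2e-13, adjusted p = 0.28 with an estimated correlation).

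Of 16 BCL2 family genes, 8 fell and 1 rose with dCBP-1, as many adjusted over the list alone. The falls took in antiapoptotic BCL2L1 (−2.92 ± 0.17) and BCL2 (−2.58 ± 0.15) as well as proapoptotic BMF (−2.46 ± 0.17) and BCL2L11 (−1.45 ± 0.14) (list camera adjusted p = 0.00027, adjusted p = 0.33 with an estimated correlation). Of 29 NF-kB targets, 11 fell and 3 rose (13 and 3 adjusted over the list alone), with the inhibitors of this pathway and of apoptosis TNFAIP3 at −3.17 ± 0.15 and BIRC3 at −2.60 ± 0.14. The median was −0.32 (camera adjusted p = 0.00091, adjusted p = 0.53 with an estimated correlation). Of 34 immediate early and CREB-responsive genes, 15 fell and 5 rose (16 and 5 adjusted over the list alone). DUSP5, DUSP4 (−4.38 ± 0.17) and PHLDA1, an apoptosis-related gene induced by growth factors (−2.38 ± 0.17), fell where EGR1 rose. The median was −0.31 (camera adjusted p = 0.0029, adjusted p = 0.68 with an estimated correlation). Of 36 genes of G2/M and mitosis, 21 rose and 4 fell, as many adjusted over the list alone, with NDC80 at 1.35 ± 0.17 and CCNB2, a mitotic cyclin, at 0.93 ± 0.14. The median was 0.42 (camera adjusted p = 0.00033, adjusted p = 0.76 with an estimated correlation). Of 31 unfolded protein response genes, 13 fell and 6 rose (14 and 6 adjusted over the list alone), with the sensor ERN1 at −2.68 ± 0.14 and its target XBP1, a plasma cell factor, at −1.84 ± 0.13. The list's call (camera adjusted p = 0.040, adjusted p = 0.89 with an estimated correlation) ended without DMSO replicate 2 (adjusted p = 0.065), DMSO replicate 3 (adjusted p = 0.077) or dCBP-1 replicate 3 (adjusted p = 0.065), under TMM (adjusted p = 0.052) and with a filter at 20 (adjusted p = 0.11).

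**Figure D4:**
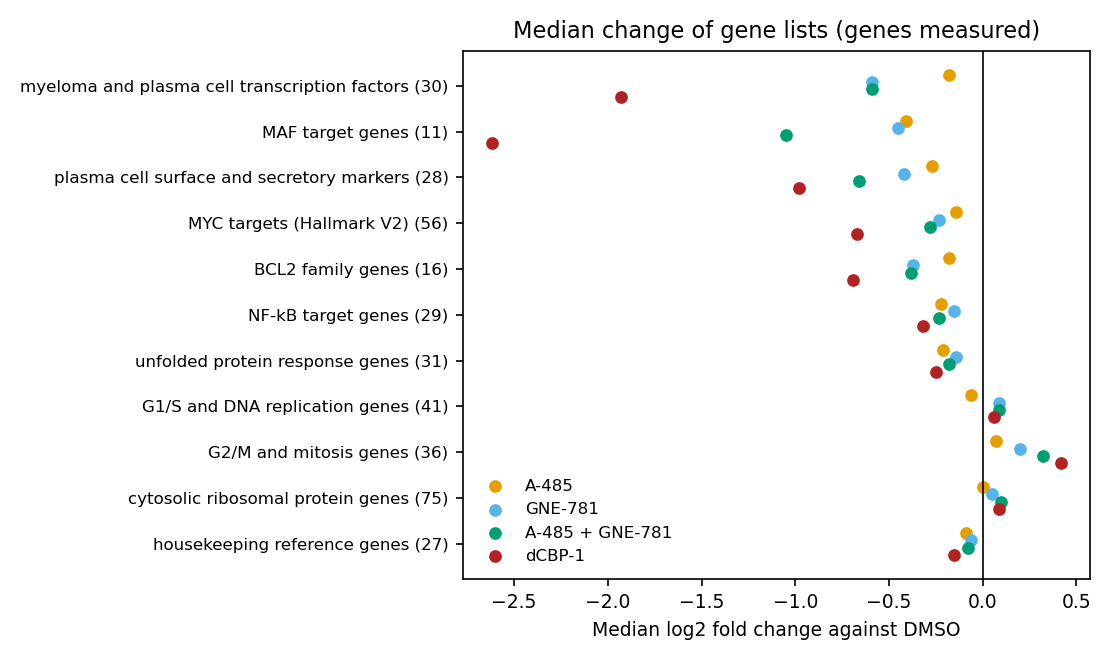
Median log2 fold change against DMSO (x axis) of the measured members of 11 gene lists (number of genes in brackets) for the 4 treatments (colours). Medians of the myeloma and plasma cell transcription factors run from −0.18 with A-485 to −1.93 with dCBP-1, and those of cytosolic ribosomal protein genes from 0 to 0.10.

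With dCBP-1, 6092 genes were called, 3105 higher and 2987 lower, 1197 and 1422 of them at least 2 fold. The split turned to 2474 higher and 2970 lower without DMSO replicate 1, 2427 and 2683 without DMSO replicate 2, and 2580 and 2743, 2597 and 2689, and 2447 and 2535 without dCBP-1 replicates 1, 2 and 3. The count was 3788 (1248 higher, 2540 lower) without DMSO replicates 1 and 2 together, where the 10 largest named rises and the 10 largest named falls all stayed called. The EP300 call ended without dCBP-1 replicate 3 (0.21, adjusted p = 0.35), DMSO replicate 2 (0.39, adjusted p = 0.11) or DMSO replicate 3 (0.35, adjusted p = 0.12), and under 7 further settings, such as median-ratio scaling (0.40, adjusted p = 0.051).

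dCBP-1 against the combination asked whether the degrader differed from both inhibitors together at the same dose and time. No DMSO library enters its fold changes, although the DMSO libraries enter the shared spread. How far the proteins were removed or blocked was not measured here. MYC was lower with dCBP-1 (log2 fold change −5.65 ± 0.33, limma adjusted p = 1.2e-13), as were TRIB1 (−5.31 ± 0.18, adjusted p = 4.1e-19), DUSP5 (−3.91 ± 0.17, adjusted p = 2.5e-16) and TENT5C, a poly(A) polymerase often mutated in myeloma (−3.49 ± 0.16, adjusted p = 2.5e-16). TRIB1 stood at 572 ± 102 with the combination, close to the 616 ± 62.3 of DMSO, and at 13.4 ± 2.28 with dCBP-1. EGR1 was higher with dCBP-1 (3.0 ± 0.24, adjusted p = 1.5e-10), as were CHAC1, a stress-induced glutathione-degrading enzyme (1.34 ± 0.15, adjusted p = 1.0e-07), ETV5 (1.28 ± 0.16, adjusted p = 4.8e-07) and MXD1, which pairs with MAX as MYC does (1.02 ± 0.17, adjusted p = 0.0001).

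Of the 30 transcription factors, 23 were lower with dCBP-1 than with the combination and 0 higher (25 lower adjusted over the list alone), with MAF at −3.17 ± 0.14 and PRDM1 at −2.80 ± 0.13. The median was −1.51 (camera adjusted p = 5.2e-55, adjusted p = 0.038 with an estimated correlation). Of 11 MAF targets, 7 were lower, the same number adjusted over the list alone, with a median of −1.51 (camera adjusted p = 4.3e-23, adjusted p = 0.0094 with an estimated correlation). These 2 calls, and that of MAF targets for dCBP-1 against DMSO, were the list calls that held with an estimated correlation. Of 56 MYC targets, 21 were lower and 0 higher (31 lower adjusted over the list alone). Their median was −0.39 (camera adjusted p = 1.4e-15, adjusted p = 0.23 with an estimated correlation). Of 28 plasma cell surface and secretory markers 12 were lower and 0 higher (13 lower adjusted over the list alone), with a median of −0.37 (camera adjusted p = 3.5e-16, adjusted p = 0.10 with an estimated correlation). CREBBP differed by 0.26 (95% interval −0.04 to 0.56; adjusted p = 0.40) and EP300 by 0.03 (−0.31 to 0.36; adjusted p = 0.97). In all 993 genes were called, 89 higher and 904 lower, 19 and 388 at least 2 fold. The split became 337 higher and 1025 lower under TMM, 330 and 1043 under median-ratio scaling and 499 and 987 under quantile normalization, and DESeq2 called 1763. The 89 higher became 39 without combination replicate 1, 33 and 43 without dCBP-1 replicates 1 and 2, and 148 with only the groups compared.

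**Figure D5:**
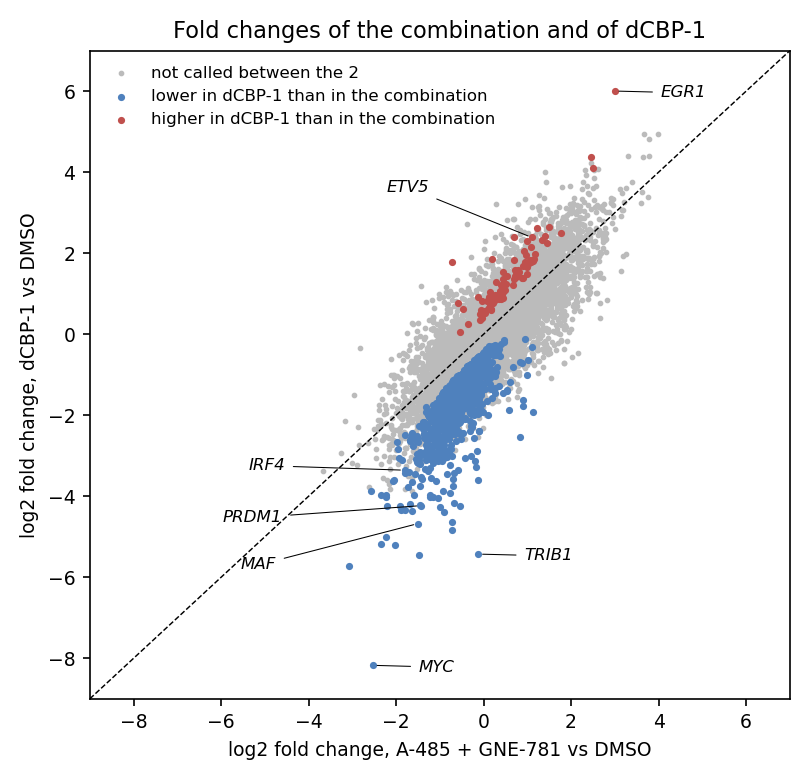
Log2 fold change against DMSO with dCBP-1 (y axis) and with the combination (x axis) for the 16104 genes tested; the dashed line marks equal change, and colours mark the 904 genes called lower and the 89 called higher in dCBP-1. MYC, TRIB1, MAF, PRDM1 and IRF4 lie below the line, and EGR1 and ETV5 above it; both axes share the same DMSO libraries.

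dCBP-1 carries a bromodomain ligand of the GNE-781 type, which sets it beside GNE-781 at 100 nM and 6 h. Against GNE-781, MYC (−6.42 ± 0.33, limma adjusted p = 4.5e-15), TRIB1 (−5.00 ± 0.18), DUSP5 (−4.09 ± 0.17) and IRF4 (−1.91 ± 0.19, adjusted p = 1.2e-08) were lower with dCBP-1. EGR1 was higher (3.56 ± 0.24, adjusted p = 2.6e-12), as were ETV5 (1.44 ± 0.16) and GBP1, an interferon-induced GTPase (1.17 ± 0.18). CREBBP differed by 0.30 (95% interval 0.00 to 0.59; adjusted p = 0.24) and EP300 by 0.10 (−0.23 to 0.44; adjusted p = 0.79). In all 1500 genes were called, 352 higher and 1148 lower, 58 and 481 at least 2 fold. The count was 2344 (1017 higher, 1327 lower) under quantile normalization, 2396 with only the groups compared and 2588 with DESeq2, and the split was 720 and 1408 under TMM. The 352 higher became 135, 165 and 201 without GNE-781 replicates 1, 2 and 3 and 154, 185 and 214 without dCBP-1 replicates 1, 2 and 3. Against A-485, dCBP-1 differed in 3947 genes, 2077 higher and 1870 lower, 551 and 864 at least 2 fold. The split turned to 1264 higher and 1796 lower without A-485 replicate 3, 1566 and 1579 without A-485 replicate 2, 1643 and 1708 without dCBP-1 replicate 1, 2109 and 2408 under TMM and 2096 and 2428 under median-ratio scaling. MYC (−7.34 ± 0.33, adjusted p = 9.8e-17), TRIB1 (−5.65 ± 0.18) and DUSP4 (−4.29 ± 0.17) were lower, and EGR1 (5.91 ± 0.24) and PGM2L1, a sugar phosphate enzyme (1.81 ± 0.21), were higher. EP300 was higher by 0.53 (adjusted p = 0.016), a call that ended without A-485 replicate 2 (0.45, adjusted p = 0.086) or dCBP-1 replicate 3 (0.34, adjusted p = 0.16).

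The inhibitors differed from each other at the same dose and time. A-485 left CCR1 higher than GNE-781 did (7723 ± 792 against 3200 ± 171 normalized read counts; log2 fold change 1.27 ± 0.13, limma adjusted p = 1.1e-06). It also left higher TP53INP1, a p53 target (1.41 ± 0.16, adjusted p = 3.5e-06), BLNK, a B cell receptor adaptor (1.21 ± 0.18, adjusted p = 0.0002), and IRF4 (1.12 ± 0.19, adjusted p = 0.0017). EGR1 (−2.35 ± 0.24, adjusted p = 1.1e-06), ETV5 (−0.90 ± 0.16, adjusted p = 0.0017) and the long noncoding RNA NEAT1 (−0.85 ± 0.15, adjusted p = 0.0027) were lower with A-485. MYC differed by 0.92 (95% interval 0.24 to 1.60; adjusted p = 0.22). In all 161 genes were called, 117 higher and 44 lower with A-485, 24 and 14 at least 2 fold. Without A-485 replicate 1 the split turned to 51 higher and 60 lower. The count was 76 and 103 without A-485 replicates 2 and 3, 57, 72 and 79 without GNE-781 replicates 1, 2 and 3, 393 under TMM, 395 under median-ratio scaling, 388 under quantile normalization, 466 with only the groups compared, 413 with edgeR and 763 with DESeq2.

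Adding GNE-781 to A-485 lowered MYC (−1.70 ± 0.33, limma adjusted p = 0.003), IRF4 (−1.48 ± 0.19, adjusted p = 1.8e-05), BLNK (−1.57 ± 0.18, adjusted p = 2.2e-06), TP53INP1 (−1.52 ± 0.16, adjusted p = 4.1e-07) and the lipase MGLL (−1.52 ± 0.20, adjusted p = 1.4e-05), and raised EGR1 (2.91 ± 0.24, adjusted p = 1.5e-08) and ETV5 (1.06 ± 0.16, adjusted p = 0.00011). The MYC call ended under a robust variance prior (adjusted p = 0.088). In all 516 genes were called, 263 higher and 253 lower, 56 and 71 at least 2 fold. Rescaling moved the median of all genes from 0.107 to near 0 and the count to 990 (283 higher, 707 lower) under TMM, 979 (271 and 708) under median-ratio scaling and 958 (362 and 596) under quantile normalization. It was 320 with no filter, 1013 with edgeR, 1406 with DESeq2, 267 (105 higher, 162 lower) and 310 (80 and 230) without A-485 replicates 2 and 3, and 187 (47 and 140) without combination replicate 2. The split was 290 and 138 without A-485 replicate 1, 257 and 149 without combination replicate 1 and 126 and 274 without combination replicate 3.

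Adding A-485 to GNE-781 gave 0 called genes with limma, with 494 at an unadjusted p below 0.05 where 805 would be expected if no gene differed. That number depended on the setting. With the same 16104 genes it ran from 335 without GNE-781 replicate 1 to 844 with only the groups compared. A number below 805 is therefore no added evidence that nothing differed. edgeR called 0 and DESeq2 5, all lower with the combination, and limma called 1 without combination replicate 3. MYC differed by −0.78 (95% interval −1.46 to −0.09; adjusted p = 1), IRF4 by −0.36 (−0.76 to 0.03), CREBBP by 0.03 (−0.26 to 0.33) and EP300 by 0.08 (−0.25 to 0.41). Of the 8052 genes at or above the median level, 99.6% had a 95% interval that lay within a 2-fold change in either direction, and the median interval reached 0.32 to each side; over all 16104 genes the share was 66.8%.

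Non-additivity asked whether the combination differed from the sum of both inhibitors on the log2 scale. NFKB2 had an interaction of 1.68 ± 0.21 (limma adjusted p = 0.00012). Its level was 1998 ± 364 with DMSO, 782 ± 143 with A-485, 705 ± 29.95 with GNE-781 and 889 ± 98.2 with the combination. SF3A2, a splicing factor, had 1.89 ± 0.27 (adjusted p = 0.00083) and TYMP, thymidine phosphorylase, whose gene overlaps SCO2, 1.78 ± 0.29 (adjusted p = 0.0037). MYC (0.05 ± 0.47, adjusted p = 0.99) and IRF4 (−0.03 ± 0.27, adjusted p = 0.99) had no called interaction. With the GC trend removed TYMP had 0.91 (adjusted p = 0.27), SF3A2 1.28 (adjusted p = 0.12) and NFKB2 1.25 (adjusted p = 0.065), and the calls of SF3A2 and TYMP also ended under median-ratio scaling (adjusted p = 0.058 and 0.059). In all 72 genes were called, 70 above and 2 below the sum, but 1 was called under TMM, median-ratio or quantile scaling, 13 with no filter and 4 with edgeR. The count was 9 and 213 without DMSO replicates 2 and 3, the last with 134 above and 79 below, 11 and 24 without A-485 replicates 1 and 2, 10 and 26 without GNE-781 replicates 1 and 2, 33 and 16 without combination replicates 1 and 3, and 2 without DMSO replicates 1 and 2 together.

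In each pair of comparisons with DMSO, most genes called for the treatment with fewer calls were called in the same direction for the other treatment. Of the 56 genes higher and 289 lower with A-485, 52 and 268 were called in the same direction with GNE-781, where independent lists would share 4.4 and 25.5. Of the 1260 higher and 1419 lower with GNE-781, 1142 and 1282 were called in the same direction with dCBP-1 (independent lists 242.9 and 263.2), and of the 1837 and 1546 with the combination, 1641 and 1461 (independent lists 354.2 and 286.8). Across genes, which are not independent replicates, fold changes correlated with a Pearson r of 0.73 between A-485 and GNE-781, 0.70 between A-485 and the combination and 0.59 between A-485 and dCBP-1. The r was 0.84 between GNE-781 and the combination, 0.78 between GNE-781 and dCBP-1 and 0.83 between the combination and dCBP-1. In 100 simulations of unchanged groups that shared a simulated DMSO group, the mean r was 0.48 to 0.52 and the highest 0.76 to 0.79. Their shared calls averaged 0 to 0.55 with a highest count of 54, but they had few calls to share, on average 2.45 to 4.34 per comparison. The highest simulated covariance was 0.233. The simulated DMSO groups drew on deviations of all 15 libraries, while the chi-square between replicates was highest, at 42.2, for DMSO replicates 1 and 3. The simulated values may therefore understate what the real DMSO libraries contribute. The observed covariance was 0.289 against a simulated mean of 0.113 for A-485 and GNE-781, 0.289 against 0.110 for A-485 and the combination, and 0.329 against 0.103 for A-485 and dCBP-1. It was 0.416 against 0.113 for GNE-781 and the combination, 0.525 against 0.105 for GNE-781 and dCBP-1, and 0.579 against 0.106 for the combination and dCBP-1. Part of the shared calls and of these correlations may come from the shared DMSO libraries, which were not split between comparisons here.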

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

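The tests of scaling, of GC content, of saturation and of other splits of the libraries in this part were chosen after the non-additive genes had been seen. The response to 1 inhibitor differed with and without the other, by a test of the interaction itself, in 72 genes. The largest interactions among the named genes were SF3A2 (1.89), SPATC1L (1.80), TYMP (1.78), NFKB2 (1.68) and MT-TV, a mitochondrial transfer RNA (1.55). SPATC1L lost its call without A-485 replicate 1 (1.5, adjusted p = 0.060) or GNE-781 replicate 1 (1.62, adjusted p = 0.065), and with the GC trend removed it had 1.12 (adjusted p = 0.27). MT-TV lost its call without DMSO replicate 2 (1.56, adjusted p = 0.078), A-485 replicate 1 (1.44, adjusted p = 0.11), A-485 replicate 2 (1.30, adjusted p = 0.090), GNE-781 replicate 1 (1.49, adjusted p = 0.099) or combination replicate 3 (1.35, adjusted p = 0.10).

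Nearly all of the 72 lay above the sum of the single responses, which may come from the scaling of the libraries, from the GC content of transcript ends or from saturation of a response that both inhibitors share. Under median-ratio scaling 1.4% of the calls (1 of 72, with 1684 genes at an unadjusted p below 0.05) were kept, the median interaction of the 72 went from 1.11 (median SE of a single gene 0.23) to 1.03 (0.24) and the smallest adjusted p of the others was 0.058. The median interaction of all genes went from 0.04 to −0.04 with the same rescaling. Rescaling thus moved the 72 little, which argues against scaling as the source of the size of their interactions. The number of calls did depend on it. With the GC trend removed limma kept 0% of the calls (0 of 72, with 1525 genes at an unadjusted p below 0.05). The median of the 72 was then 0.81 (0.22), so GC content stays open. For saturation, the 234 genes lower with each inhibitor had a median interaction 0.68 above that of all genes, against a mean of 0.16 and a highest value of 0.40 in 50 simulated additive draws. The 234 were chosen as lower than DMSO, which enters the interaction with a plus sign. The draws took deviations from all 15 libraries, while the chi-square between replicates was highest for DMSO replicates 1 and 3. A high DMSO error in these genes can therefore not be told apart from saturation, which stays a hypothesis.

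DMSO enters the interaction too, and without DMSO replicates 1 and 2 together 2 genes were called, while without DMSO replicate 3 there were 213, 134 above and 79 below, so the share above the sum went from 97.2% to 62.9%. Of 100 splits of the 12 libraries, 5 gave 72 genes or more and the highest other count was 3142, but such splits put the differences between treatments into the interaction, so they do not decide on chance.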

How the results depend on the processing

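Removal of the GC trend, the fits without DMSO replicates 1 and 2 together, edgeR and DESeq2 between treatments, and median-ratio scaling of the correlations were chosen after seeing the data. Over all settings, the named genes kept their side of the threshold in 11717 comparisons with an alternative, lost the call in 663, gained it in 204 and reversed in 1. Lists did so in 1519, 82, 24 and 0. A reversal was counted only where the gene or list was called in the main fit or the alternative. Changes of sign in entries called in neither are among those kept. Counts of genes stayed within 1.5 times in 155 and moved further in 65, and correlations of fold changes stayed within 1 SD of their values with 1 library left out in 39 and moved further in 27. The reversed value was GPS1, GNE-781 vs DMSO, at −0.44 and, with the GC trend removed, 0.019 (adjusted p = 0.91). The cause was not tested for any value in this part, except that leaving out libraries leaves fewer. Scaling to spike-ins and the spike-in share were not run.

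The 345 genes of A-485 against DMSO became 178 with no filter, 78 with only the groups compared, 852 with DESeq2 and 12 without DMSO replicates 1 and 2 together. Without those 2 libraries, GNE-781 had 883 instead of 2679, the combination 1064 instead of 3383 and dCBP-1 3788 instead of 6092. With only the groups compared the combination had 2163. Leaving out each library in turn gave 69 to 1138 for A-485, 1467 to 3689 for GNE-781, 2050 to 4277 for the combination and 4982 to 6457 for dCBP-1. Called leading members of lists kept their call without any 1 library in 6 of 36 for A-485, 68 of 94 for GNE-781, 81 of 91 for the combination and 94 of 97 for dCBP-1.

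Between treatments, dCBP-1 against the combination had 1763 with DESeq2 instead of 993 (691 to 987 leaving out each library in turn), and dCBP-1 against A-485 had 3056 to 3761 instead of 3947. dCBP-1 against GNE-781 (1500) had 2344 under quantile normalization, 2396 with only the groups compared, 2261 with the GC trend removed, 2588 with DESeq2 and 1033 to 1154 leaving out each library. The combination against A-485 (516) had 990, 979 and 958 under TMM, median-ratio and quantile scaling, 320 with no filter, 1085 with the GC trend removed, 1013 with edgeR, 1406 with DESeq2 and 187 to 428 leaving out each library. The combination against GNE-781 (0 with limma, 494 at an unadjusted p below 0.05) had 0 with edgeR, 5 with DESeq2 and 0 to 1 leaving out each library. A-485 against GNE-781 (161) had 393, 395 and 388 under the 3 scalings, 466 with only the groups compared, 439 with the GC trend removed, 413 with edgeR, 763 with DESeq2 and 57 to 111 leaving out each library. Non-additivity (72) had 1, 1 and 1 under the 3 scalings, 13 with no filter, 4 with edgeR, 2 without DMSO replicates 1 and 2 together and 9 to 213 leaving out each library. With the GC trend removed limma gave 0, with 1525 at an unadjusted p below 0.05, where edgeR without that step gave 4 and DESeq2 107.

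Replicate numbers were tried as a block, although residuals gave little sign of pairing. They were correlated over genes at or above the median level. Over 30 pairs of libraries with the same number in different groups the correlation ran from −0.527 to 0.397 and was above 0.1 in 7. Averaged by number, the correlation was highest with the own number in 0 of 15 libraries, and the single highest correlation was with the own number in 4. The block gave 107 genes for A-485 against GNE-781 and 34 for non-additivity, and EP300 with dCBP-1 against DMSO, 0.406 in both fits, had an adjusted p of 0.066. It moved no other count of genes by over 1.5 times.

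EP300, dCBP-1 vs DMSO, at 0.406, lost its call with a pseudocount of 0.25 (adjusted p = 0.054), no filter (0.11) or only the groups compared (0.069), under median-ratio scaling (0.400), with the GC trend removed (0.350) and without DMSO replicates 1 and 2 together (0.517). Leaving out each library gave 0.213 to 0.523 there and 0.336 to 0.645 for dCBP-1 against A-485. EP300, A-485 + GNE-781 vs A-485 ranged over 0.374 to 0.658 and EP300, A-485 + GNE-781 vs DMSO over 0.252 to 0.536. CREBBP, GNE-781 vs DMSO had 0.397 and CREBBP, A-485 + GNE-781 vs DMSO 0.432 without DMSO replicates 1 and 2 together, with ranges of 0.441 to 0.628 and 0.475 to 0.660. CREBBP, dCBP-1 vs GNE-781 had 0.361 and a call under quantile normalization (adjusted p = 0.0361), and 0.187 to 0.389 leaving out each library.

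Lists past the threshold numbered 12 for A-485, 11 for GNE-781, 10 for the combination, 10 for dCBP-1 and 9 for dCBP-1 against the combination, and with an estimated correlation 0, 0, 0, 1 and 2. Correlations of fold changes at or above the median level were 0.820 for A-485 and GNE-781, 0.794 for A-485 and the combination, 0.645 for A-485 and dCBP-1, 0.938 for GNE-781 and the combination, 0.850 for GNE-781 and dCBP-1 and 0.893 for the combination and dCBP-1. Under median-ratio scaling all genes gave 0.730, 0.704, 0.590, 0.840, 0.781 and 0.830 in the same order. Leaving out each library gave 0.678 to 0.821, 0.656 to 0.797, 0.551 to 0.678, 0.790 to 0.886, 0.741 to 0.820 and 0.793 to 0.859 in this order.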

Other observations

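In this part the splits of the libraries and the tests on the A-485 calls of all 3 DMSO libraries, on those with no further call, on GC content, on median-ratio scaling, on the direction of calls without dCBP-1 replicate 3 and on the ERK pathway were chosen after the results had been seen. Further gene groups were counted for dCBP-1 against DMSO. Of 18 histone deacetylase genes 4 rose and 5 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.75), with HDAC9 at −2.84 and HDAC4 at −1.42. Of 34 acetyltransferase or bromodomain genes, CREBBP and EP300 included, 11 rose and 4 fell (11 and 5 over the list alone; camera adjusted p = 0.38), with BRD8 at 1.26 and ATAD2 at 0.82. Of 43 interferon-stimulated genes 12 rose and 12 fell (12 and 13; camera adjusted p = 0.65), with IRF2 at −2.11 and IRF1 at −1.12. Of 17 MHC genes 0 rose and 5 fell (4 over the list alone; camera adjusted p = 0.091, and 0.033 with no filter), with CIITA, which activates MHC class II genes, at −4.34 and HLA-DRA at −0.86. Of 41 genes of G1/S and replication 11 rose and 8 fell, as many over the list alone (camera adjusted p = 0.88), with CCND1 at −4.22, CCND2 at −3.06 and CDK6 at −2.49. Of 25 p53 targets 8 rose and 6 fell, as many over the list alone (camera adjusted p = 0.74), with TP53INP1 at −2.64 and BTG2 at −1.66. Cholesterol genes had 8 higher and 7 lower of 27, as many over the list alone (camera adjusted p = 0.95), with SREBF1 at −1.48 and ACAT2 at 1.16. Glycolysis and hypoxia genes had 4 higher and 11 lower of 30 (5 and 11; camera adjusted p = 0.13), with SLC2A3 at 2.42 and ANKRD37 at −2.52.

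Among the remaining groups, RNA polymerase II pause and elongation genes had 9 higher and 9 lower of 34 with dCBP-1 (9 and 10 over the list alone; camera adjusted p = 0.96), with ELL at −1.35 and AFF4 at 0.93. Histone genes with HEXIM1 had 2 higher and 3 lower of 12 (2 and 4; camera adjusted p = 0.67), with H2BC21 at 1.78 and HEXIM1 at 0.78, whose call ended without DMSO replicates 1 and 2 together (0.49, adjusted p = 0.11). Cereblon ligase genes had 2 higher and 3 lower of 17 (1 and 3; camera adjusted p = 0.62), with the ubiquitin-conjugating enzyme UBE2G1 at −1.22. Cytosolic ribosomal protein genes had 9 higher and 10 lower of 75 (8 and 10; camera adjusted p = 0.70) and respiratory chain genes of the nucleus 6 higher and 5 lower of 39 (5 and 5; camera adjusted p = 0.88). Mitochondrially encoded genes, whose share of reads was highest in DMSO replicates 1 and 2, had 0 higher and 6 lower of 15, as many over the list alone (camera adjusted p = 0.030, adjusted p = 0.68 with an estimated correlation). That call ended without DMSO replicate 1 (adjusted p = 0.11) or dCBP-1 replicate 2 (adjusted p = 0.077). Housekeeping genes had 1 higher and 8 lower of 27, as many over the list alone (camera adjusted p = 0.16). Markers of other lineages had 2 higher and 2 lower of 11, as many over the list alone (camera adjusted p = 0.99). KRT18 had 0 reads in each DMSO library and 21 in each dCBP-1 library, and HBB fell (−1.58).

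With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Every split other than the real one mixes the 2 groups. A difference between the groups then enters the spread and can lower the count, so these splits do not decide on chance. For A-485 against DMSO 2 splits gave 345 genes or more, with a highest other count of 429. The real split was the 1 with as many for GNE-781 (2679), the combination (3383) and dCBP-1 (6092) against DMSO, for dCBP-1 against the combination (993), A-485 (3947) and GNE-781 (1500), for the combination against A-485 (516) and for A-485 against GNE-781 (161), each with a highest other count of 0. For the combination against GNE-781 (0 with limma and edgeR, 5 with DESeq2, 494 at an unadjusted p below 0.05) all 10 gave as many, with a highest other of 1.

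The calls for A-485 may in part come from DMSO replicates 1 and 2, which stand apart. Without DMSO replicate 3 there were 1138 calls, and against that held-out library a median of 17.1% of their difference remained (48.4% for GNE-781, 51.5% for the combination, 73.8% for dCBP-1), which is what that explanation needs for these calls. Of the 345 calls made with all 3 DMSO libraries a median of 73.5% remained, which leaves it open there because DMSO replicate 3 helped to choose them, and 67.8% (234 of 345) kept their call with the GC trend removed, which leaves GC content open. A difference of the DMSO libraries alone as the cause of all 345 is argued against, since between A-485 and dCBP-1, where no DMSO library enters the fold change, 151 moved again in the same direction and 8 moved back, but it stays open for the 186 that were not called there. Inhibition of the acetyltransferase stays among the open explanations.

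dCBP-1 was lower than the combination far more often than higher. Under median-ratio scaling 24.0% of calls were higher (330 higher, 1043 lower), under quantile normalization 33.6% and with DESeq2 33.1% (583 higher, 1180 lower). Lower calls stayed the majority in each, so the choice among these scalings is argued against as the whole cause. The share did depend on that choice. With no spike-ins, scaling as a part of the cause stays open. Without dCBP-1 replicate 3, 76.8% of calls were kept (763 of 993, against 749 and 738 without replicates 1 and 2) and 8.9% of calls were higher, against 9.0% with it, which argues against that library as the source of the direction. A hypothesis is that the degrader may extend the direction of the inhibitor responses: 88.5% of the called genes had the same sign in GNE-781 against DMSO, a comparison with no library in common. Of the higher calls 86.5% did, where 56.2% of all genes were higher, and of the lower calls 88.7%, where 43.8% were lower. These shares count signs only. Of the 904 lower calls, 444 were also called lower with GNE-781 against DMSO and 1 was called higher. Across all genes the fold changes of these 2 comparisons correlated at 0.29, and at 0.52 for genes at or above the median level.

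EGR1 and ETV5 were higher with dCBP-1, and raised output of the ERK pathway could account for that. Of 9 measured genes of a 10-gene list of ERK output, 1 was higher (ETV5, 2.39) and 4 were lower (DUSP4 −4.38, CCND1 −4.22, PHLDA1 −2.38 and DUSP6 −0.96), while SPRY4 (2.0, adjusted p = 0.08), ETV4 (1.78, adjusted p = 0.065), EPHA4 (1.58, adjusted p = 0.11) and SPRY2 (0.16, adjusted p = 0.84) were not called. ETV5 had raised the question, so its rise cannot count for the hypothesis, and every other called member was lower. The uncalled members had positive folds with wide errors (SE 0.90 for SPRY4 and 0.51 for SPRY2). With 5 positive and 4 negative folds, ETV5 included, the list does not decide, and the hypothesis stays open.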
